A study of Homo sapiens with 12 samples.

How the data were processed

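LNCaP, an androgen-sensitive human prostate cancer cell line, was starved of hormone over 72 h in RPMI free of phenol red that held 3% CCS, and was then treated for 16 h, per the labels' protocols. The treatments were vehicle, 10 nM dihydrotestosterone (DHT, an androgen), 10 µM A4B17, which the labels describe as an inhibitor of BAG1L, or DHT and A4B17 together, called the combination here. BAG1L is a long protein form made from the BAG1 gene. There were 3 libraries in each of the 4 groups, 12 in all, made from total RNA with the NEBNext Ultra kit and sequenced as paired ends on an Illumina platform, per the labels' protocols. The labels number the libraries but do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

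The authors deposited 1 table with 1 column for each library. The table is named as counts, but its values are FPKM, a fragment measure scaled to transcript length and library size, as the deposited values show. No more than 0.0249% of the values of any library were whole numbers above 0 (with a tolerance of 0), and the library totals lay between 432711 and 513897. The genome build was hg19, per the submitters' processing notes. The aligner, the counter, the gene annotation and the strand setting are not given in the sources used here. Values of genes with near-identical copies or close paralogs, among them KLK2 and KLK3, TUBA3D, the HSPA1, UGT2B and AKR1C families and the metallothioneins, are uncertain for that reason. The reference genome at hand was of another build, so no coordinates are given.

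The absolute depth of the libraries is unknown, because FPKM values keep no read totals. Relative depth was estimated from genes with low values, whose ratios between libraries fall on ratios of small whole numbers when 1 fragment has a fixed worth. It ran from 0.939 to 1.22 of the first vehicle library. Between 59.4% and 67.0% of such genes lay on whole ratios within 0.02 on the log2 scale, against 18.1% to 20.0% at other offsets. Intervals and detection floors that need counts were therefore not computed.

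Of 20111 rows, 28 had symbols turned into dates and were left out; they held at most 0.125% of the FPKM of any library. Another 3068 genes were at 0 in all 12 libraries. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 11531. Values were put on the log2(FPKM + 1) scale with a pseudocount of 1, and every fold change is on that scale, which understates changes of low genes. The design written before the data were examined named a count test for counts and limma for normalized values. Because the values are FPKM, the second was used: limma 3.58.1 in R 4.3.3, with an intensity trend, 1 term for each of the 4 groups and no other covariate, all 12 libraries in the fit. p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Adjusted p-values of genes below come from this model. The same software was tested on simulated data with known changes. For DHT against vehicle it recovered 73% of 100 genes changed by a log2 of 1 and 100% of 100 changed by a log2 of 2, and called 6 unchanged genes among 11531. For A4B17 against vehicle it recovered 73% and 99% and called 6 unchanged genes. Both runs drew the same noise, independent between libraries and with the same spread in every group. The real A4B17 libraries varied more, with a median standard deviation of a gene of 0.25 log2 units against 0.15 for vehicle. Over libraries 2 and 3 alone these values were 0.15 and 0.12, so most of the excess came with library 1. The recovered shares therefore do not tell how many changes the A4B17 comparisons could find.

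The 5 planned comparisons were DHT against vehicle, the combination against DHT, A4B17 against vehicle, the combination against vehicle, and the interaction, which is the change with A4B17 in DHT-treated cells minus that in vehicle-treated cells. The combination against A4B17 was added after seeing the data. The genes named were fixed by rule. For each pairwise comparison they were the 10 genes with the largest change each way among those past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the 3 libraries of each group, which chance gives in 10% of genes. For the interaction they were the 5 largest each way. KLK3, KLK2, TMPRSS2, FKBP5 and BAG1 were always named, with up to 4 members of each list with the smallest p. Some genes that the rule names are not reported here. TSC22D3 and VLDLR for the combination against DHT, FN1, and the single-library values of FOS, DDIT3, CDKN1A and MT-CYB were chosen after their values were seen.

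Before the data were examined, 26 gene lists with 573 members were fixed, of which 568 were in the table. The 21 lists with at least 5 genes tested went through camera, a limma test that sets a list against all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 105 list tests. The 21 list tests of the added comparison were adjusted apart. Each call was repeated with an estimated correlation between genes and with fry. Mainly the value with an estimated correlation is printed below. Of 46 list calls in the planned comparisons, 6 passed with it and 17 with fry. The share of the DHT response left with A4B17 was the median over genes, changed at least 2-fold by DHT, of the change in the combination divided by the change with DHT, set beside 100 simulations with no effect of A4B17. Both changes were taken against vehicle, so an effect of A4B17 without DHT enters the share. In simulated data where 40% was put in, the share came out at 42.3% over 234 genes.

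Libraries with the same number deviated together in 2 comparisons. In DHT against vehicle, the correlations across genes of the deviations from the group means were 0.55, 0.20 and 0.60, and for the combination against A4B17 they were 0.84, 0.75 and 0.70. The pairing comes from the data, since no label says what a number marks, and the value with the number as a block is given beside both results and beside the interaction, which is their difference. The block was 1 effect of the number common to all 4 groups, so a number effect that differed between groups was not modeled. Alternatives tried were other thresholds, pseudocounts and filters, only the groups of a comparison, the block, and leaving out each library. A median-of-ratios scaling and leaving out sets of same-numbered libraries were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.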

Results

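Transcript levels were measured in LNCaP cells, a human prostate cancer line that responds to added androgen. The series, whose title concerns prostate cancer therapy, compared 4 groups of 3 libraries after 16 h. These were vehicle, 10 nM DHT, 10 µM A4B17, and DHT with A4B17. The deposited values were FPKM, with totals between 432711 and 513897 per library, and the read depth behind them is unknown beyond relative depths of 0.939 to 1.22. Of 20111 rows, 11531 genes were tested.

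The libraries differed by DHT, by A4B17, and by a feature that set number 1 of both A4B17-treated groups apart. The first principal component held 47.0% of the variance and the second 22.4%. On the first component, A4B17 libraries 2 and 3 lay at 36.4 and 32.1 and combination libraries 2 and 3 at 33.2 and 30.96, while A4B17 library 1 lay at -15.8 and combination library 1 at -19.2. Vehicle libraries lay at -23.9, -16.6 and 0.612, and DHT libraries at -30.5, -22.5 and -4.82. The Spearman correlation across genes of A4B17 library 1 was 0.987, 0.988 and 0.976 with the vehicle libraries, but 0.941 and 0.942 with the other A4B17 libraries; genes are not independent replicates. The median standard deviation of a gene within a group was 0.15 log2 units for vehicle, 0.16 for DHT, 0.25 for A4B17 and 0.25 for the combination. Over libraries 2 and 3 alone it was 0.12, 0.14, 0.15 and 0.15 in the same order. The smallest mean absolute log2 difference between any pair of libraries was 0.16, so no pair held the same values.

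**Figure D1:**
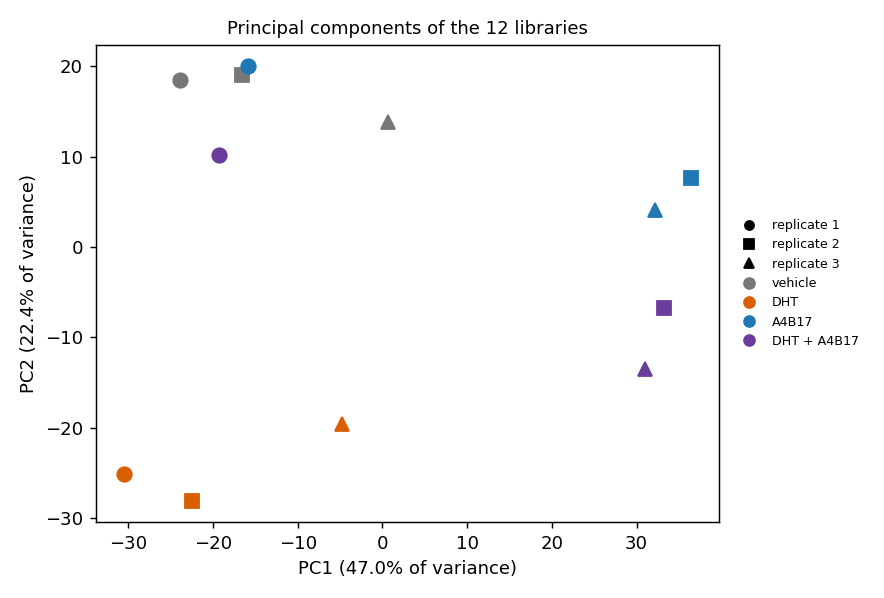
First and second principal components of the 12 libraries on the log2(FPKM + 1) scale, in arbitrary units, with a color for each group and a symbol for each library number. A4B17 and combination libraries numbered 1 lie at -15.8 and -19.2 on the first component, and the other A4B17-treated libraries between 30.96 and 36.4.

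DHT against vehicle asked which transcripts answered the androgen alone. KLK3, which encodes prostate-specific antigen, rose from 9.77 ± 3.61 to 109 ± 26.2 FPKM (mean ± SD, n = 3 each), a 10.3-fold change (log2 3.37, SE 0.26, limma adjusted p = 3.03e-05). The related kallikrein KLK2 rose 24.4-fold (log2 4.61, SE 0.35), from 3.54 ± 1.81 to 106 ± 17.8 FPKM, although reads shared between these paralogs leave their split uncertain. NCAPD3, a condensin subunit, had the largest rise among the genes named, 44.2-fold (log2 5.46, SE 0.38), from 15.5 ± 2.91 to 772 ± 318 FPKM. FKBP5, a co-chaperone of steroid receptors, rose 18.9-fold (log2 4.24, SE 0.42) and the protease gene TMPRSS2 rose 8.67-fold (log2 3.12, SE 0.46). Among 28 core androgen targets tested, 26 rose and 0 fell; 27 rose and 0 fell when adjusted over the list alone.

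Other core targets that rose were STEAP4 (log2 2.43), ADAMTS1 (log2 2.52) and the efflux transporter ABCC4 (log2 2.04). Further large rises were those of TUBA3D (log2 3.76), HPGD, which inactivates prostaglandins (log2 3.65), the GTPase RHOU (log2 3.63), the natriuretic peptide gene NPPC (log2 3.29) and the EGF receptor inhibitor ERRFI1 (log2 3.13). TUBA3D has near-identical copies, so its value is uncertain. NPPC did not pass without any one of the 6 libraries compared (adjusted p between 0.0517 and 0.138), nor ERRFI1 without vehicle library 1 (0.0688), vehicle library 2 (0.0680) or DHT library 2 (0.0918).

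BAG1 did not pass the test with DHT, at 19.1 ± 3.93 FPKM in vehicle and 17.4 ± 3.65 in DHT (log2 -0.13, SE 0.24, limma adjusted p = 0.881). Of 20 genes in a list that includes the BAG family and hormone receptor cofactors, GRHL2 rose (log2 0.98) and the other 19 did not pass.

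Some genes of lipid and polyamine synthesis rose with DHT. Of 24 cholesterol synthesis genes 4 rose and 0 fell, among them IDI1 (log2 1.40) and SC5D (log2 1.03); the median of the list was 0.74, and its adjusted p was 1.63e-13 in camera and adjusted p = 0.248 with an estimated correlation. Adjusted over the list alone, 8 of the 24 rose. Of 18 fatty acid synthesis genes 5 rose and 0 fell, among them ACSL3 (log2 2.75), ELOVL7 (log2 2.33), ELOVL5 (log2 1.05) and ACACA (log2 0.89), with a list median of 0.43 and adjusted p = 0.0817 with an estimated correlation; adjusted over the list alone 8 rose and 1 fell. Of 9 polyamine synthesis genes 3 rose: ODC1 (log2 2.18), the first enzyme of the pathway, SMS (log2 1.83) and AMD1 (log2 1.10). That list had a median of 0.12 and a mean of 0.72, and adjusted p = 0.0908 with an estimated correlation; 3 rose adjusted over the list alone. Its median was 0.26 without vehicle library 1, -0.01 without vehicle library 3, 0.07 without DHT library 1 and 0.35 without DHT library 3.

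Of 20 genes of the unfolded protein response, DNAJC3 (log2 1.11) and DNAJB9 (log2 1.39) rose and 18 did not pass, with a list median of 0.77 and adjusted p = 0.336 with an estimated correlation; 10 rose when adjusted over the list alone. That list lay at 1.30, 1.04 and 0.04 above the vehicle mean in DHT libraries 1, 2 and 3, and its median was 0.51 without DHT library 1. The broad androgen response list had 52 of 99 genes higher and 0 lower, or 70 and 0 adjusted over the list alone, with a median of 1.04 and adjusted p = 0.0089 with an estimated correlation. The median of the core list was 2.44, with an adjusted p of 6.08e-56 in camera and adjusted p = 0.0089 with an estimated correlation. VLDLR rose (log2 1.76) as the only gene to pass among 22 of the ATF4 list, and ANKRD37 (log2 1.42) as the only gene to pass among 22 of the hypoxia list. Neither list was called, although the hypoxia list was with the library number as a block (adjusted p = 0.0306 in camera at the preset correlation). Without the block the hypoxia list had adjusted p = 0.589 with an estimated correlation.

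Transcripts lower with DHT included LPPR1 (log2 -2.37, SE 0.36), FAM198B (log2 -1.74), the transcription factor gene ZIC2 (log2 -1.72), CNKSR3 (log2 -1.72) and TMEM144 (log2 -1.69). SLC44A1, a choline transporter gene, fell by 1.66 on the log2 scale, the growth factor adapter gene GRB10 by 1.62, SEMA3C by 1.56 and SLC12A2 by 1.46. Of 10 androgen-repressed genes tested, DDC fell (log2 -1.47) and 9 did not pass; 2 were lower adjusted over the list alone, the list median was -0.62, and the list was not called (adjusted p = 0.0949 in camera). At the preset correlation it was called with median-of-ratios scaling (adjusted p = 0.0430) and with the library number as a block (adjusted p = 0.0339). In the main fit it had adjusted p = 0.756 with an estimated correlation. GCLC (log2 -1.16), which makes a glutathione precursor, fell alone among 18 NRF2 targets, TP53INP1 (log2 -1.22) alone among 22 p53 targets, and fibronectin FN1 (log2 -0.57) alone among 4 stromal genes; the NRF2 and p53 lists were not called and the stromal list was too small to test. The 11 interferon genes had a median of -0.26 with 0 past the test singly (adjusted p = 0.284 with an estimated correlation). That call ended without vehicle library 1 (adjusted p = 0.0592), vehicle library 3 (0.121), DHT library 1 (0.0532) or DHT library 2 (0.0564). The 30 ribosomal protein genes had a median of -0.14 (adjusted p = 0.959 with an estimated correlation), a call that ended with median-of-ratios scaling (adjusted p = 0.0972) and without vehicle library 3 (0.434), DHT library 1 (0.764) or DHT library 2 (0.0934). Without DHT library 3 the median was -0.25.

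In all, 384 of 11531 genes changed between DHT and vehicle, 273 higher and 111 lower, of which 172 and 46 changed at least 2-fold (limma, Benjamini-Hochberg). With the library number as a block 1039 genes passed, 565 higher and 474 lower. The count was 226 without vehicle library 1, 177 without vehicle library 2, 237 without vehicle library 3, 199 without DHT library 1 and 144 without DHT library 2; 21 of the 40 changed genes named here passed in all 23 refits, and STEAP4 in the 19 that tested it, which leave out a filter at 5 FPKM and the refits without a DHT library. Among the 12 refits without a single library, the call ended in 11 for FN1 (adjusted p up to 0.243), in 8 for DNAJB9 (up to 0.218), in 7 for IDI1, DDC, SLC12A2 and TP53INP1 (up to 0.220), in 6 for DNAJC3 and NPPC (up to 0.189) and in 5 for GRHL2 (up to 0.125). It ended in 4 for FAM198B, TMEM144 and GCLC, in 3 for AMD1 and ERRFI1, in 2 for ACACA, ANKRD37 and SEMA3C, and in 1 for CNKSR3 (up to 0.117).

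**Figure D2:**
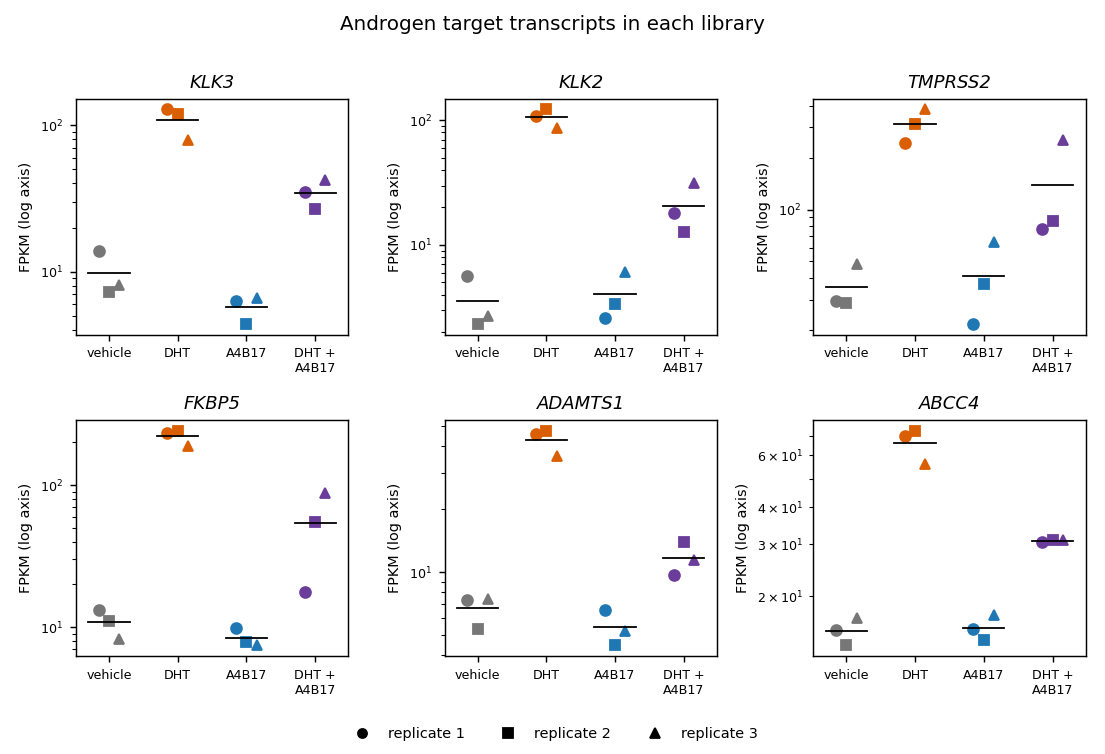
FPKM of 6 androgen targets in each library, on log axes, with groups along the horizontal axis, symbols for the library number and horizontal lines for the mean of 3 libraries. KLK3 had means of 9.77 FPKM in vehicle, 109 in DHT, 5.79 in A4B17 and 34.6 in the combination.

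DHT with A4B17 against DHT asked what the compound did to androgen-treated cells. KLK3 fell from 109 ± 26.2 to 34.6 ± 7.62 FPKM (n = 3 each; log2 -1.62, SE 0.26, limma adjusted p = 0.0101), and KLK2 from 106 ± 17.8 to 20.7 ± 9.51 (log2 -2.38, SE 0.35, limma adjusted p = 0.0066). NCAPD3 fell from 772 ± 318 to 61.1 ± 27.0 FPKM (log2 -3.66, SE 0.38), and FKBP5 from 221 ± 28.4 to 53.8 ± 35.5 (log2 -2.28, SE 0.42, limma adjusted p = 0.0210). Of 28 core androgen targets 18 fell and 1 rose; the 1 was TSC22D3 (log2 0.68), a gene also known as a glucocorticoid target. Adjusted over the list alone 26 fell and 1 rose. TMPRSS2 was at 312 ± 69.2 and 139 ± 99.8 FPKM (log2 -1.36, limma adjusted p = 0.174) and did not pass.

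Other androgen-responsive genes that fell were NDRG1 (log2 -2.60), TUBA3D (log2 -2.55), the acyl-CoA synthetase gene ACSL3 (log2 -2.46), the lipid phosphatase gene PPAP2A (log2 -2.28), HPGD (log2 -2.26), RHOU (log2 -2.24) and the centromere gene CENPN (log2 -2.22). STEAP4 (log2 -2.16), MAF (log2 -2.05), ADAMTS1 (log2 -1.80), the kinase gene SGK1 (log2 -1.73), the luminal keratin gene KRT8 (log2 -1.73) and ABCC4 (log2 -1.07) fell too. BAG1 was at 23.3 ± 3.03 FPKM with the combination and 17.4 ± 3.65 with DHT (log2 0.42, SE 0.24, limma adjusted p = 0.380).

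The median of the core list was -1.49, with an adjusted p of 5.34e-30 in camera and adjusted p = 0.0189 with an estimated correlation; the differences of its medians were -1.63, -1.94 and -1.02 for libraries of number 1, 2 and 3. The broad androgen list had 35 of 99 genes lower and 0 higher, or 54 lower and 1 higher adjusted over the list alone, with a median of -0.66 and adjusted p = 0.0349 with an estimated correlation. KLK3 did not pass without DHT library 1 (adjusted p = 0.0746), DHT library 2 (0.0763) or combination library 2 (0.0566), nor KLK2 without DHT library 2 (0.0515), nor FKBP5 without DHT library 1 (0.111), DHT library 2 (0.133) or combination library 2 (0.0667).

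Some lipid synthesis genes fell with the combination relative to DHT. Of 24 cholesterol synthesis genes 7 fell and 0 rose, among them HMGCS1 (log2 -1.84) and IDI1 (log2 -1.80); 20 fell adjusted over the list alone, and the median was -0.995 (adjusted p = 0.140 with an estimated correlation). Of 18 fatty acid synthesis genes 3 fell, ACSL3, ELOVL7 (log2 -1.64) and the desaturase gene FADS2 (log2 -1.18), with a median of -0.66 (adjusted p = 0.0717 with an estimated correlation); 12 fell and 1 rose adjusted over the list alone. ODC1 (log2 -1.88) and SMS (log2 -1.52) fell among 9 polyamine genes, a list that was not called (adjusted p = 0.0810 in camera). The 20 unfolded protein response genes had 0 past the test singly and a median of -0.48 (adjusted p = 0.638 with an estimated correlation), which was -0.31 without DHT library 1 and -0.78 without DHT library 3. HSPE1 (log2 -0.57), a mitochondrial chaperonin, and ANKRD37 (log2 -1.60) fell alone among 24 heat shock and 22 hypoxia genes, and neither list was called.

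Some genes of the ATF4 and amino acid response rose. Of 22 tested 7 rose, among them ASNS (log2 1.18), which makes asparagine, the serine synthesis genes PHGDH (log2 0.81) and PSAT1 (log2 0.78), SHMT2 (log2 0.61), CTH (log2 1.25) and SESN2 (log2 1.55). The lipoprotein receptor gene VLDLR fell (log2 -1.20), and 14 rose and 1 fell adjusted over the list alone; the list median was 0.84 (adjusted p = 0.126 with an estimated correlation). The list median of the combination minus DHT was 0.80, 0.91 and 0.87 in the pairs of number 1, 2 and 3. Other genes higher with the combination were the kinase gene FYN (log2 2.08), CNKSR3 (log2 2.04), DGKH (log2 1.71), RFX3 (log2 1.46), SEMA3C (log2 1.39), SLC7A2 (log2 1.36), PKIB (log2 1.35) and RNF187 (log2 1.21).

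Among lists with 0 genes past the test singly, the 22 p53 targets had a median of 0.69 (adjusted p = 0.638 with an estimated correlation) and pair values of 0.36, 1.09 and 0.54. The 9 mitochondrially encoded genes had a median of -0.63 (adjusted p = 0.589 with an estimated correlation) and pair values of 0.04, -1.21 and -0.69. Their median was -0.99 without combination library 1 and -0.36 without combination library 2. The 10 immediate early and NF-kappaB genes, not called, had pair values of -0.02, 1.36 and 0.80. The 11 interferon genes had a median of 0.29, with 4 higher adjusted over the list alone (adjusted p = 0.129 with an estimated correlation), and the 30 ribosomal protein genes had a median of 0.29 (adjusted p = 0.624 with an estimated correlation).

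In all, 186 genes changed between the combination and DHT, 54 higher and 132 lower, of which 20 and 80 changed at least 2-fold (limma, Benjamini-Hochberg). The fit took a common spread over all groups, although the median standard deviation was 0.16 for DHT and 0.25 for the combination. Over libraries 2 and 3 alone it was 0.14 and 0.15. With only the groups compared, 36 genes passed, 5 higher and 31 lower. The count was 713 without combination library 1, with 358 higher and 355 lower, and it was 64 without combination library 2, 45 without DHT library 1, 32 without DHT library 2 and 121 without vehicle library 2. Without both A4B17-treated libraries numbered 1, an alternative chosen after seeing the data, it was 2567, with 1441 higher and 1126 lower, so that most were no longer lower; without both numbered 2 or both numbered 3 it was 50 and 113. Of the 41 changed genes named here 10 passed in all 23 refits: NCAPD3, TUBA3D, ACSL3, RHOU, CENPN, MAF, KRT8, ADAMTS1, ABCC4 and ELOVL7. STEAP4 and SGK1 passed in the 19 that tested them, which leave out a filter at 5 FPKM and the refits without a DHT library. Among the 12 refits without a single library, the call ended in 9 for HSPE1 (adjusted p up to 0.172), in 8 for SESN2 and TSC22D3 (up to 0.234), in 7 for CTH, in 6 for SEMA3C, in 5 for NDRG1, VLDLR and SLC7A2, in 4 for HMGCS1, IDI1, FADS2, ASNS, SHMT2, DGKH and RNF187, and in 1 to 3 for 12 others.

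Of the 273 genes higher with DHT, 110 were among the 132 that fell when A4B17 was added, against 3.13 for independent lists. Of the 111 lower with DHT, 23 were among the 54 that rose, against 0.520. Both comparisons use the DHT libraries, which alone push them in opposite directions; in 20 simulations with an effect of DHT only the first overlap was at most 1, and with no effect of either it was 0. Part of the excess may come from the shared libraries. Across genes the fold changes had a correlation of -0.59, with -0.50 simulated without effects, and a covariance of -0.0908, with -0.0261 simulated and -0.0108 from the deviations of same-numbered libraries.

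Over 172 genes raised at least 2-fold by DHT, a median of 34.7% of the log2 response was left with A4B17 (SD 10.5 over 3 combination libraries, with 23.8%, 36.4% and 44.6% for numbers 1, 2 and 3). The baseline was vehicle, so a fall with A4B17 alone counts as lost response. The core androgen list had a median of 0.75 for the combination over vehicle. Over A4B17 of the same number it was 0.91, 1.09 and 1.17, beside 2.29, 2.66 and 2.08 for DHT over vehicle. Simulated libraries with no effect of A4B17 gave 96.1%, with a range of 93.0% to 98.9% over 100 simulations. Over 46 genes lowered at least 2-fold the share was 42.6% (SD 18.0, n = 3; 26.4%, 43.1% and 62.3%), against a simulated 88.7% with a range of 81.3% to 93.1%. LPPR1 was at 8.63 ± 0.927 FPKM in vehicle, 0.918 ± 0.613 in DHT and 1.98 ± 1.93 in the combination.

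**Figure D3:**
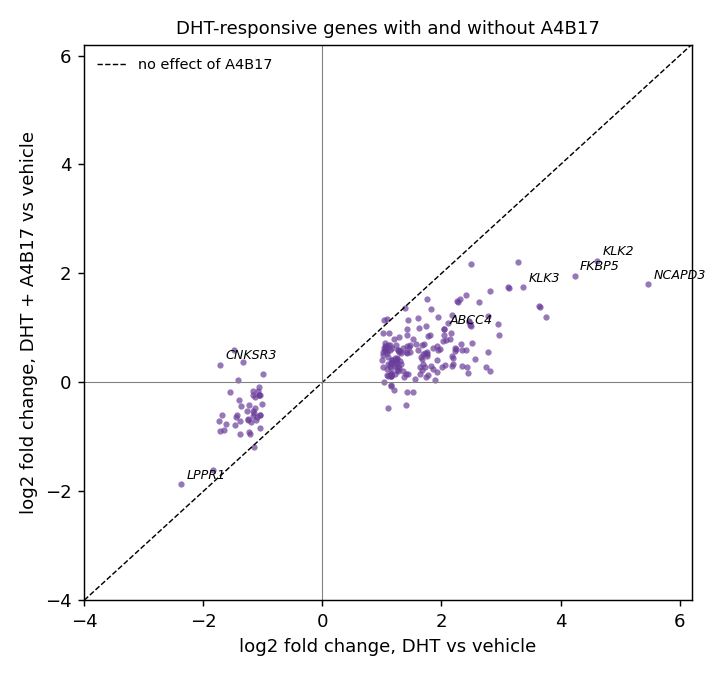
Log2 fold change against vehicle with DHT (horizontal axis) and with DHT and A4B17 (vertical axis) for the genes changed at least 2-fold by DHT, each point a gene and the dashed line no effect of A4B17. NCAPD3 had 5.46 with DHT and -3.66 between the combination and DHT, and 34.7% of the response of the 172 raised genes was left.

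A4B17 against vehicle asked what the compound did with no androgen added. No gene passed the limma test at a Benjamini-Hochberg adjusted 0.05 (0 of 11531, smallest adjusted p = 0.554), with 921 genes at an unadjusted p under 0.05. KLK3 was at 9.77 ± 3.61 FPKM in vehicle and 5.79 ± 1.22 in A4B17 (n = 3 each; log2 -0.63, SE 0.26, limma adjusted p = 0.554), KLK2 at 3.54 ± 1.81 and 4.02 ± 1.83 (log2 0.15), TMPRSS2 at 35.5 ± 11.1 and 41.4 ± 22.1 (log2 0.12), and FKBP5 at 10.9 ± 2.48 and 8.38 ± 1.31 (log2 -0.33). BAG1 was at 19.1 ± 3.93 and 25.3 ± 9.78 (log2 0.35, limma adjusted p = 0.568), and KLK4 had a log2 difference of -0.70 and SLC45A3 of -1.36.

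As a group, the ATF4 and amino acid genes were higher with A4B17 in camera (adjusted p = 1.35e-11, or 0.0766 with an estimated correlation). With fry the adjusted p was 0.0115. Their median was 0.77, 20 of 22 had a positive value, and 13 were higher adjusted over the list alone, PHGDH (log2 0.48), CTH (log2 1.18), SHMT2 (log2 0.51) and ASNS (log2 0.97) among them by smallest p. The list differed from the vehicle library of its number by 0.74, 0.93 and 0.58. The core androgen targets had 0 genes past the test, 20 of 28 below vehicle, and a median of -0.20 (adjusted p = 0.624 with an estimated correlation).

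Other lists differed between the A4B17 libraries. The 10 immediate early and NF-kappaB genes, which include JUNB (log2 1.84), DUSP1 (log2 1.20) and MYC (log2 -0.85), had a median of 0.78 (adjusted p = 0.515 with an estimated correlation) but 0.07 in the pair numbered 1 against 1.39 and 1.02 in pairs 2 and 3. The call ended without A4B17 library 2 (adjusted p = 0.0556). FOS was at 0.630 FPKM in A4B17 library 1, 37.1 in library 2 and 4.76 in library 3, and at most 1.03 in vehicle. The 22 p53 targets, among them GDF15 (log2 2.26) and PLK3 (log2 0.94), had a median of 0.40 (adjusted p = 0.638 with an estimated correlation), with 0.08, 0.75 and 0.57 by pair, a call that ended without A4B17 library 3 (adjusted p = 0.0658); CDKN1A was at 19.8, 156 and 212 FPKM in A4B17 libraries 1, 2 and 3. The 9 mitochondrially encoded genes had a median of -0.66 (adjusted p = 0.589 with an estimated correlation) with 0.34, -1.25 and -0.96 by pair. MT-CYB (log2 -0.96) was at 921, 270 and 251 FPKM in those libraries, and MT-ND2 had a log2 difference of -0.84. The 10 androgen-repressed genes, with 0 past the test singly, had a median of -0.53 (adjusted p = 0.471 with an estimated correlation) with -0.10, -1.09 and -0.55 by pair. Without A4B17 library 1 the medians of these lists were 1.20 for immediate early, 0.68 for p53, -1.10 for mitochondrial and -0.89 for androgen-repressed genes. Without A4B17 library 2 they were 0.50 for immediate early, -0.37 for mitochondrial and -0.29 for androgen-repressed genes. Without A4B17 library 3 they were 0.27 for p53 and -0.35 for androgen-repressed genes.

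Further lists called in camera with 0 genes past the test singly were cholesterol synthesis at -0.29 (adjusted p = 0.634 with an estimated correlation) and fatty acid synthesis at -0.22 (adjusted p = 0.471 with an estimated correlation). The S phase list was called at -0.22 (adjusted p = 0.767 with an estimated correlation) and the ribosomal protein genes at 0.12 (adjusted p = 0.787 with an estimated correlation). Cholesterol synthesis was at -0.16 without A4B17 library 2. The fatty acid call ended without vehicle library 3 (adjusted p = 0.125), A4B17 library 1 (0.102) or A4B17 library 2 (0.0700), the S phase call without vehicle library 1 (0.364) and the ribosomal call without A4B17 library 3 (0.0720). Without A4B17 library 1 the S phase list was at -0.37 and the ribosomal list at 0.21. The count of genes was 0 with any single library left out. Without both A4B17-treated libraries numbered 1, chosen after seeing the data, 2088 genes passed, 1156 higher and 932 lower; without both numbered 2 or both numbered 3 it was 0.

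**Figure D4:**
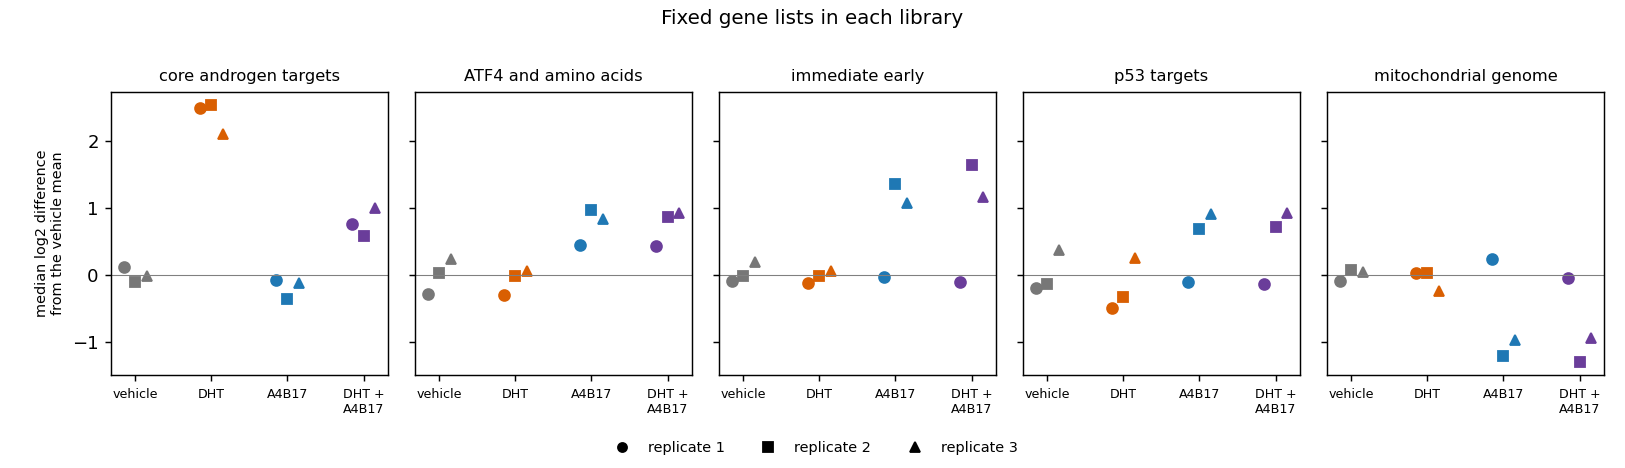
Median log2 difference from the vehicle mean of 5 gene lists in each library, with groups along the horizontal axis and symbols for the library number. The core androgen list in combination libraries lies at 0.75, 0.57 and 0.99 and in DHT libraries at 2.49, 2.54 and 2.10; A4B17 library 1 lies at 0.45 for the ATF4 list.

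DHT with A4B17 against vehicle asked what was left of the androgen response. ABCC4 rose from 15.3 ± 1.61 to 30.8 ± 0.323 FPKM (1.96-fold; log2 0.97, SE 0.13) and GPT2, an alanine aminotransferase gene, from 31.5 ± 2.58 to 59.0 ± 2.21 (1.85-fold; log2 0.89, SE 0.12), each at a limma adjusted p of 0.0499 (n = 3). KLK3 was at 34.6 ± 7.62 FPKM against 9.77 ± 3.61 (log2 1.75, limma adjusted p = 0.0721) and KLK2 at 20.7 ± 9.51 against 3.54 ± 1.81 (log2 2.23, limma adjusted p = 0.0721), and neither passed. TMPRSS2 (log2 1.76, limma adjusted p = 0.316), FKBP5 (log2 1.96, limma adjusted p = 0.20) and BAG1 (log2 0.29, limma adjusted p = 0.551) did not pass.

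The core androgen targets had 1 gene higher, ABCC4, and 15 adjusted over the list alone, with 26 of 28 above vehicle and a median of 0.75 (adjusted p = 0.0720 with an estimated correlation). The broad list had 1 gene higher, or 27 higher and 1 lower adjusted over the list alone, with a median of 0.34 (adjusted p = 0.104 with an estimated correlation). The ATF4 list had 0 genes past the test, 12 adjusted over the list alone, and a median of 0.70 (adjusted p = 0.0817 with an estimated correlation). Also called in camera were the androgen-repressed genes, with a median of -0.69 (adjusted p = 0.520 with an estimated correlation), and cholesterol synthesis at -0.33 (adjusted p = 0.787 with an estimated correlation). Polyamine synthesis was called at 0.31 (adjusted p = 0.340 with an estimated correlation) and the unfolded protein response at 0.22 (adjusted p = 0.756 with an estimated correlation). The p53 targets at 0.49 (adjusted p = 0.645 with an estimated correlation), ribosomal protein genes at 0.16 (adjusted p = 0.756 with an estimated correlation) and mitochondrially encoded genes at -0.77 (adjusted p = 0.589 with an estimated correlation) were called too.

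Some of these lists differed between the combination libraries. Against the vehicle mean, libraries 1, 2 and 3 lay at -0.14, 0.71 and 0.92 for p53 targets, at -0.05, -1.31 and -0.95 for mitochondrially encoded genes and at -0.12, -0.95 and -1.03 for androgen-repressed genes. They lay at 0.03, -0.73 and -0.39 for cholesterol synthesis, at -0.01, 0.19 and 0.29 for ribosomal protein genes and at 0.45, 0.30 and 0.04 for the unfolded protein response. Without combination library 1 the p53 median was 0.81 and the ribosomal median 0.25, and without combination library 2 the mitochondrial median was -0.48. Without combination library 3 the ribosomal median was 0.08 and the unfolded protein response median 0.41. The unfolded protein response median was 0.38 without vehicle library 1. The cholesterol call ended without vehicle library 1 (adjusted p = 0.118) or combination library 2 (0.458), and the polyamine call without vehicle library 3 (0.0725) or combination library 2 (0.0590). The unfolded protein response call ended without vehicle library 3 (0.181) or combination library 1 (0.170).

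The 2 changed genes were the whole count, beside 1426 at an unadjusted p under 0.05. It was 742 without combination library 1, 2 without DHT library 3 and 0 without any other single library; without both A4B17-treated libraries numbered 1 it was 2686, and without both numbered 2 or both numbered 3 it was 0.

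The interaction asked whether the change with A4B17 differed between DHT-treated and vehicle-treated cells. It was negative for 7 genes and positive for 0 (limma, Benjamini-Hochberg; 507 at an unadjusted p under 0.05), and with the library number as a block it was negative for 38 and positive for 2. The stomach protease gene PGC (log2 -2.19, SE 0.25, limma adjusted p = 0.00926) was at 7.35 ± 0.622 FPKM with DHT and 0.987 ± 0.537 with the combination, and at most 0.150 FPKM in any vehicle or A4B17 library. STEAP4 (log2 -2.15), MAF (log2 -1.98), SGK1 (log2 -1.85), KRT8 (log2 -1.80), RHOU (log2 -2.37) and CENPN (log2 -2.44) were the others, and all 7 were among the genes DHT raised. The DHT and vehicle libraries enter both comparisons with opposite signs, which favors that overlap. STEAP4 and SGK1 reached 1 FPKM only in the DHT group, which left little room for a fall without DHT. KLK2 (log2 -2.53, limma adjusted p = 0.102), KLK3 (log2 -0.98, limma adjusted p = 0.925) and FKBP5 (log2 -1.95, limma adjusted p = 0.720) did not pass, nor did TMPRSS2 (log2 -1.48) or BAG1 (log2 0.07).

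The core androgen targets had a median interaction of -1.11, with 1 gene lower singly and 18 adjusted over the list alone (adjusted p of 2.03e-35 in camera; adjusted p = 0.0135 with an estimated correlation). The broad list had a median of -0.64, with 5 lower and 35 adjusted over the list alone (adjusted p = 0.0135 with an estimated correlation). The lists of the unfolded protein response at -0.68 (adjusted p = 0.386 with an estimated correlation), cholesterol synthesis at -0.59 (adjusted p = 0.235 with an estimated correlation) and fatty acid synthesis at -0.40 (adjusted p = 0.0817 with an estimated correlation) were called with 0 genes past the test singly. So were polyamine synthesis at -0.12 (adjusted p = 0.0911 with an estimated correlation), ribosomal protein genes at 0.17 (adjusted p = 0.787 with an estimated correlation) and androgen-repressed genes at 0.46 (adjusted p = 0.638 with an estimated correlation). With the block the hypoxia list (adjusted p = 0.0190) and the nuclear genes of oxidative phosphorylation (adjusted p = 0.0339) were called in camera as well. Both calls rest on the preset correlation, since an estimated correlation was not run with the block. The androgen-repressed call ended without vehicle library 1 (0.102), vehicle library 2 (0.0907), DHT library 3 (0.115), A4B17 library 2 (0.343), A4B17 library 3 (0.116) or combination library 1 (0.502). The ribosomal call ended without vehicle library 3 (0.103), DHT library 1 (0.230), A4B17 library 1 (0.316) or combination library 3 (0.190). The median of the unfolded protein response was -0.43 without vehicle library 3, -0.38 without DHT library 1 and -1.03 without DHT library 3, and that of polyamine synthesis reached -0.32 without A4B17 library 1. The count of 7 was 0 without vehicle library 1, vehicle library 2, DHT library 1 or DHT library 2, 2 without vehicle library 3, A4B17 library 2 or A4B17 library 3, and 3 without combination library 2. It was 14 without combination library 3, 32 without DHT library 3, and 0 with a pseudocount of 0.1 or a filter at 5 FPKM.

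DHT with A4B17 against A4B17, a comparison added after seeing the data, gave the DHT response in the presence of the compound. KLK3 rose from 5.79 ± 1.22 to 34.6 ± 7.62 FPKM (5.22-fold; log2 2.38, SE 0.26, limma adjusted p = 0.0122), ENDOD1, a nuclease-domain gene, from 11.2 ± 2.82 to 34.5 ± 9.18 (log2 1.53, SE 0.19, limma adjusted p = 0.0210) and ABCC4 from 15.6 ± 1.57 to 30.8 ± 0.323 (log2 0.94, SE 0.13, limma adjusted p = 0.0466; n = 3 each). These 3 were the whole count, beside 304 at an unadjusted p under 0.05, and 20 genes passed with the library number as a block. The block took 1 effect of the number common to all 4 groups. On the first component, however, A4B17 minus vehicle was 8.04, 52.9 and 31.5 for numbers 1, 2 and 3. A fit within the numbers of these groups alone was not run. Neither count therefore tells how many genes answered DHT in the presence of A4B17. KLK2 (log2 2.08, limma adjusted p = 0.104), FKBP5 (log2 2.29, limma adjusted p = 0.141) and TMPRSS2 (log2 1.64, limma adjusted p = 0.741) did not pass, but with the block KLK2 (adjusted p = 0.0489) and TMPRSS2 (adjusted p = 0.0235) did.

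All 28 core androgen targets had a positive value, with a median of 1.10 and pair values of 0.91, 1.09 and 1.17; 2 rose singly and 22 adjusted over the list alone (adjusted p = 0.00103 with an estimated correlation). The broad list had 2 higher, or 24 adjusted over the list alone, and a median of 0.25 (adjusted p = 0.00822 with an estimated correlation). Fatty acid synthesis was called upward in camera although its median was -0.01 and its mean 0.08 (adjusted p = 0.742 with an estimated correlation), a call that ended with the block (adjusted p = 0.0646). The unfolded protein response (adjusted p = 0.00581) and S phase (adjusted p = 0.0206) lists were called upward in camera with the block alone. Those calls rest on the preset correlation, since an estimated correlation was not run with the block. The count of 3 was 20 without combination library 1, 5 without A4B17 library 1, 2 without combination library 2, 1 without vehicle library 1, vehicle library 3, DHT library 1 or DHT library 2, and 0 without A4B17 library 2, A4B17 library 3 or combination library 3.

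Several lists were called in no comparison without the block: heat shock and chaperone genes, mitosis genes, aryl hydrocarbon receptor targets, NRF2 targets, nuclear genes of oxidative phosphorylation, hypoxia and glycolysis genes, and the list that includes the BAG family and hormone receptor cofactors. Mitosis genes had medians of -0.02 with DHT and 0.06 with A4B17 against vehicle. Lists with fewer than 5 genes tested were the metallothioneins with 4, stromal genes with 4, neuroendocrine markers with 2, leukocyte and endothelial genes with 1, and basal epithelial genes with 1. For A4B17 against vehicle their medians were 0.23, -0.01, -0.40, 0.31 and 0.51.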

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

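The regroupings of libraries without the block were planned before the data were examined, and the other tests in this part were chosen after the results were seen.

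The change with A4B17 differed between DHT-treated and vehicle-treated cells for 7 genes by the interaction test. The log2 interaction was -2.44 for CENPN, -2.37 for RHOU, -2.19 for PGC, -2.15 for STEAP4, -1.98 for MAF, -1.85 for SGK1 and -1.80 for KRT8. PGC was barely detected in libraries without DHT, so a fall with A4B17 could not show there. STEAP4 and SGK1 lay below 1 FPKM in every library outside the DHT group, so a fall without DHT had little room to show. Over the refits that tested them, their log2 interactions ran from -3.84 to -0.504 and from -3.52 to -0.405. The count depended on the scale: it was 0 with a pseudocount of 0.1 or a filter at 5 FPKM, and 22 with a pseudocount of 10. By the same contrast, list medians were -1.11 for core androgen targets, -0.64 for the broad androgen response, -0.59 for cholesterol synthesis, -0.40 for fatty acid synthesis, -0.68 for the unfolded protein response, -0.12 for polyamine synthesis, 0.46 for androgen-repressed genes and 0.17 for ribosomal protein genes. Of 100 draws of the 12 libraries, the real grouping included, 5 gave at least 7 genes, and the highest other draw gave 4289. With the library number as a block 40 genes passed. Of 100 draws within the numbers, the real grouping included, 4 gave at least as many, and the highest other gave 1084. Such draws carry the effects of DHT and of A4B17 into the interaction. They therefore cannot tell whether chance gave either count, and chance was not excluded.

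The libraries numbered 1 of both A4B17-treated groups lay near those without the compound. Combination library 1 without any A4B17 is argued against, since its core androgen targets lay at -1.63 log2 units from DHT library 1 while the DHT libraries spanned 0.439. A batch that moved all libraries numbered 1 alike is argued against as well, since the first component of A4B17 minus vehicle had a range of 44.9 over the numbers against 1.18 for DHT minus vehicle. A weaker exposure that scales every change alike is argued against in both groups by the lists that follow. In the pair of the combination and DHT numbered 1, the ATF4 list reached 91.6% of the smaller change in the other pairs. The immediate early list reached -1.95%, which left 93.6 percentage points between them. Both lists were chosen after their values were seen. A4B17 minus vehicle parted the lists in the same way. There the ATF4 list was at 0.74 in number 1, beside 0.93 and 0.58 in numbers 2 and 3. The immediate early list was at 0.07, beside 1.39 and 1.02. For the combination minus DHT, the core androgen targets were at -1.63 in number 1, between -1.94 and -1.02 in numbers 2 and 3. A4B17 library 1 without the compound is argued against by its number, since its ATF4 list lay 0.745 above vehicle library 1, more than the range of 0.536 over the 6 libraries without A4B17, although no label says what a number marks and without regard to it the list lay at 0.445 above the vehicle mean and the highest vehicle library at 0.239. A difference in time, dose or culture that moved the immediate early, p53 and mitochondrial genes but not the androgen targets may remain, and it was not tested.

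The androgen targets were lower with A4B17 beside DHT. Scaling of the libraries is argued against, since the core list had a median of -1.55 with median-of-ratios scaling and -1.49 without it. A by-product of the immediate early, p53 and mitochondrial changes stays open: the pair numbered 1 lacked the immediate early change and its targets still differed by -1.63, but that is 1 pair. An action of A4B17 on BAG1L, which the labels' description would give, may account for the pattern and was not tested.

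The splits of the 6 libraries of a comparison, the real one included, number 10, too few for a share under 0.05. DHT against vehicle gave 384 genes and at most 0 in another split, with the real one the 1 split as large; the combination against DHT gave 186 and at most 0, again 1 split. A4B17 against vehicle gave 0 in all 10 splits, and the combination against vehicle gave 2 against at most 1. For the combination against A4B17, 2 of the 10 splits gave at least 3 genes, and the highest other gave 264. That split set A4B17 libraries 1 and 3 and combination library 1 against the rest, which points to a structure of the libraries. Among the 4 splits that part all pairs, in the paired comparisons the highest other count was 0.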

How the results depend on the processing

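The scaling by median of ratios and the left-out sets of same-numbered libraries were chosen after seeing the data, and the other settings before. Directions held: of 93 changed values of named genes 0 reversed, 31 passed in all 23 refits, 3 passed in the 19 that tested them, and of 46 list calls in the 5 planned comparisons 0 reversed. Those calls numbered 6 with an estimated correlation, 17 with fry, 46 with the replicate block and 45 with median-of-ratios scaling, and between 40 and 45 without a single library. The core androgen list kept its camera call for DHT against vehicle, the combination against DHT and the interaction. Planned count-based size factors, the DESeq2 Wald test, voom and CPM filters were not run because the values are FPKM; depth is unknown, so what it limits could not be computed. Without a library an arm of 2 is assumed to vary like the other groups. The cause of the moves below was not tested, apart from the stricter thresholds, which give fewer calls by construction.

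Counts are given in the order DHT against vehicle, combination against DHT, A4B17 against vehicle, combination against vehicle, interaction, combination against A4B17. They were 384, 186, 0, 2, 7 and 3 as reported. At an adjusted p under 0.01 they were 181, 54, 0, 0, 2 and 0, and with a fold of at least 2 they were 218, 100, 0, 0, 7 and 2. With only the groups compared they were 681, 36, 0, 0 and, for the last, 0. Pseudocount 0.1 gave 383, 176, 0, 0, 0 and 5, and pseudocount 10 gave 379, 204, 0, 0, 22 and 2. No filter gave 372, 152, 0, 0, 6 and 4, a filter at 5 FPKM 316, 160, 0, 2, 0 and 3, and median-of-ratios scaling 416, 205, 0, 0, 16 and 4.

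With the replicate block they were 1039, 1555, 13, 176, 40 and 20. Of the changes between the combination and DHT, 54 were higher and 132 lower as reported, while 59.0% were higher with the block (917 higher and 638 lower) and 58.7% without all libraries numbered 1 (609 and 429). The numbers did not pair the libraries of the combination against DHT (correlations 0.42, 0.04 and 0.48), A4B17 against vehicle (0.47, -0.03 and 0.57) or the combination against vehicle (0.43, -0.01 and 0.57), where 2 of 3 numbers correlated best with their own; the block ended none of the 46 list calls. It added NRF2 targets for A4B17 against vehicle (adjusted p = 0.0171), and the S phase (0.0380) and immediate early (0.0339) lists for the combination against vehicle. These camera calls rest on the preset correlation, since an estimated correlation was not run with the block. Without the block the NRF2 list for A4B17 against vehicle had adjusted p = 0.989 with an estimated correlation. Without both A4B17-treated libraries numbered 1 the counts were 766, 2567, 2088, 2686, 3 and 13. Without both numbered 2 they were 360, 50, 0, 0, 0 and 1, without both numbered 3 they were 350, 113, 0, 0, 1 and 0, and without all libraries numbered 1 they were 252, 1038, 630, 1312, 0 and 8. Without a single library they ranged from 144 to 521, 32 to 713, 0 to 0, 0 to 742, 0 to 32 and 0 to 20.

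The share of the DHT response left ranged without a single library from 29.0% to 39.6% for raised genes and from 33.6% to 57.2% for lowered genes; for lowered genes it was 63.4% without all libraries numbered 1. Values that had not passed changed sign as follows, with the range without a single library. BAG1 with DHT ranged from -0.28 to 0.024. With A4B17 against vehicle and without both libraries numbered 3, KLK2 was -0.13 (-0.13 to 0.46) and TMPRSS2 -0.27 (-0.27 to 0.50). BAG1 in the interaction was -0.048 without both numbered 1, -0.0057 without both numbered 3 and -0.042 without all numbered 1 (-0.085 to 0.36).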

Other observations

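All values in this part were chosen after the results were seen.

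The fold changes of A4B17 with and without DHT, which share no library, had a correlation across genes of 0.62. Same-numbered libraries deviated together, and their deviations from the group means give a correlation of 0.55 with no common effect; the covariance was 0.0802, with 0.0226 from those deviations. The fold changes of DHT with and without A4B17 had a correlation of 0.60, a covariance of 0.0464, and 2.75e-04 from the deviations. Genes are not independent replicates. DDIT3, a stress transcription factor gene, was at 43.1, 581 and 304 FPKM in A4B17 libraries 1, 2 and 3 and at 41.6, 591 and 333 in the combination, against 17.2, 24.5 and 56.4 in vehicle. PSAT1 did not follow that order, with 142, 112 and 118 FPKM in A4B17 libraries 1, 2 and 3. In the combination it was at 149, 111 and 115, against 66.5, 76.8 and 72.5 in DHT.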
